A study of Mus musculus with 8 samples.

How the data were processed

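Total RNA from snap-frozen cortex and hippocampus of naive mice was amplified and labelled with Agilent's QuickAmp kit from 0.5 µg per sample, WT with Cy3 and KO with Cy5, per the labels. A 2-colour array carries 1 sample in each dye. The files of the 2 samples named with the same tissue and number were byte-identical in all 4 pairs, so the 8 samples are the 2 channels of 4 arrays, all on 1 slide and from 1 scan. Slide and scan therefore give no batch to test. The labels do not say whether replicates are separate animals or whether cortex and hippocampus of one number share an animal.

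The deposited scanner intensities were made with Feature Extraction 10.1.1.1, per the file headers, which give for each spot the mean signal, the median of the local background, a processed signal that is background-subtracted and dye-normalised, and marks for spots well above background, saturated or outlying. The log10 ratio of Cy5 over Cy3 in those files is Feature Extraction's own, per the file headers, and was used only to check the deposited value table. That table holds log2 values per channel made by the authors. Its column medians were 8.21 to 8.25, the mean of both channels had the same distribution on all 4 arrays, and its log ratios had r = 0.947 to 0.971 across spots with the loess log ratios of the same arrays, in the direction KO over WT, and r = 0.645 to 0.708 with Feature Extraction's. The background correction and the role of limma, which the submitters' processing notes name, are not given in the sources used here. The scanner files name genes by symbol and give mm9 positions, per the file headers.

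Signals were read in R 4.3.3 with the data.table package (1.17.8) and fitted with limma 3.58.1. The background was corrected with normexp (offset 50) on the mean signal and the background median, and each array was normalised with loess (span 0.3) with the 1377 control spots at weight 0. Of 44397 spots, the 43020 others hold 39429 probes, 30497 of them with a symbol and 22898 distinct symbols. Spots of one probe were averaged. Each gene was represented by its brightest probe over all arrays, and was kept if well above background on both arrays of at least 1 of the 4 groups, which left 16365 genes after 20 were left out for outlying spots. Accessions of 14766 of these genes matched the RefSeq table, which was used for names only, and 1538 current symbols differ from those of the array. Names in the text are those of the array.

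One step of the fit was changed after its first gene counts had been seen, so that 2 versions were run. In the first version normexp used every background value and gave a background mean of -3509 in the Cy5 channel of cortex replicate 1 and -726 in that of cortex replicate 2, where single spots had backgrounds up to 642060 and 33469 against a median of 54. The log ratios of the 10 spike-in RNAs, which should be alike on all arrays, then differed between arrays by up to 1.15, and this prompted the change. In the version reported, the background of spots that Feature Extraction marks as having an outlying local background (166 in the Cy5 channel of cortex replicate 1) was replaced by the array's median background, after which the spike-ins differed by up to 0.28. The range between arrays fell for a minority of the spike-ins, most for E1A_r60_a97 (1.15 to 0.14). It rose for the majority, most for E1A_r60_a107 (0.08 to 0.28). After the change every spike-in had its highest log ratio on cortex replicate 1, with -1.11 for E1A_r60_a107 against -1.35 to -1.39 on the other arrays. The spike-ins thus do not favour the version reported throughout. The first version called 0 genes in cortex (1659 at an unadjusted p under 0.05 in limma), 7 in hippocampus, 3 in the mean of both tissues, 0 in their difference, and 1796 and 1999 between tissues in WT and KO, where the version reported called 10, 3, 1795, 0, 2484 and 2467. The number of genes called in the mean of both tissues thus rests on a choice made after seeing the data, and the first version is given among the alternatives.

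The median signal over that of the negative controls was 1.35 to 1.43 in Cy3 and 3.24 to 3.66 in Cy5, so weakly expressed genes were measured better in KO than in WT. Within an array, spike-in ratios followed the known ratios with a slope of 0.92. Log ratios of single arrays had r = 0.32 to 0.64 with one another across genes. A probe well above background on neither array of a group has only a bound there. Its fold is given as at least N-fold, from the brighter group's mean against the higher of the probe's own level and the lowest level among probes well above background on each array, after loess and Aquantile. These bounds are open to dye bias, since no dyes were swapped.

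KO and WT were compared by lmFit and eBayes on the 4 log ratios with 1 mean per tissue, giving cortex, hippocampus, the mean of both and their difference (2 residual and 2.62 prior degrees of freedom). Cortex and hippocampus were compared within WT and within KO by limma's single-channel fit (lmscFit) after loess and Aquantile, with an intraspot correlation of 0.192. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. In the mean of both tissues p-values are too small if the cortex and hippocampus of one number came from one animal.

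Of 31 gene lists, fixed with the tests, groups and all alternatives but 2 before the data were examined, 30 were tested with camera (preset correlation 0.01) and adjusted over the 30, while the sex-linked markers are described gene by gene. None of camera's calls held with an estimated correlation, in any of the 6 comparisons. Fry, which asks whether a list's genes move on balance one way, called 0 lists in the 4 KO comparisons and 5 and 7 in the tissue comparisons. For the tissue comparisons camera and fry used the 8 channels without the array as a block. The study's own list of 6 activity-regulated genes is known from its publication and was chosen on these samples. The text names Tet1, Tet2 and Tet3, the 8 largest rises and falls among called genes with one sign on all arrays concerned (filled up by smallest p where fewer passed), up to 4 members of smallest p of each list described, the study's list and the sex-linked markers. Symbols of predicted genes and clones were left out of the largest changes, and a few genes that meet this rule in the tissue comparisons are not reported here.

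The fits and list tests were tried on simulated values under the real gene names and mean intensities, some genes changed by a known amount. Values were drawn independently between genes, with spreads from the fitted prior that the model itself assumes. Earlier processing steps and dye bias were not simulated, so the rates hold for that setting and not for the real arrays. At a log2 change of 1 the procedure recovered 70.1% of changed genes in cortex, 73.1% in hippocampus, 89.6% in the mean, 41.8% in the difference, and 80.6% and 83.6% in the tissue comparisons of WT and KO. At 0.5 it recovered 1.49%, 2.99%, 58.2%, 1.49%, 46.3% and 31.3%. Of the unchanged genes it called 6, 2, 3, 6, 20 and 15. A simulated list of 40 genes shifted by -0.5 passed camera in the first 3 comparisons, but had an adjusted p = 0.142, 0.167 and 0.114 with an estimated correlation, so that this setting missed a shift that was there. Alternatives covered the background correction, the normalisation, the filter on dim probes, the probe per gene, the variance model, the samples in the fit, each array left out, the array or the replicate number as a block, the authors' value table and the list test. The first version of the background correction and the single-channel fit of KO against WT were added to these after seeing the data.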

Results

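Gene expression was measured in the cortex and hippocampus of wild-type (WT) mice and of mice lacking Tet1 (KO). Tet1 is a dioxygenase that oxidises 5-methylcytosine in DNA, and the design asks which transcripts differ in brain tissue without it. The tissue came from naive mice of a mixed strain background. The 8 samples form 4 groups of 2, and each WT sample, labelled with Cy3, shared 1 of 4 two-colour arrays with a KO sample labelled with Cy5. All 4 arrays lay on 1 slide and were scanned together. Spots well above background made up 49.7% to 51.7% of an array in the Cy3 channel and 66.6% to 67.2% in the Cy5 channel, no spot was saturated, and 16365 genes were tested. The number of arrays limits the precision of every value. Where replicates are not stated to be separate animals, as here, p-values measure only the spread between these samples, which may be technical.

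Values are log2 ratios of KO over WT with the SE of the limma fit (n = 2 arrays per tissue), and probe positions are those of mouse build mm9. WT was Cy3 and KO was Cy5 on all 4 arrays, so a KO to WT ratio also carries any dye bias of its probe. A bias equal on all arrays cancels in the difference between tissues, and cortex and hippocampus were compared within one dye. Loess normalisation left the median of all genes at 0.04 in cortex and 0.02 in hippocampus, while centring each array on its median in place of loess put it at 0.54 and 0.53. Changes under that centring are therefore given here relative to these medians. This does not correct genes that the centring moved otherwise than the median.

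The targeted gene did not pass the threshold in either tissue. The brightest Tet1 probe (chromosome 10, 62274448 to 62274507) was well above background in all 8 samples and gave -0.18 and -0.20 on the cortex arrays and -0.23 and -0.10 on the hippocampus arrays. The mean was -0.19 ± 0.07 in cortex (adjusted p = 0.223) and -0.17 ± 0.07 in hippocampus (adjusted p = 0.232). Under median centring it was larger relative to the median of all genes, with -0.48 and -0.44. Its WT signals in Cy3 were only 470 to 532, against medians of 247 to 263 for the negative controls. Subtracting a single median does not correct a shift that depends on intensity, so the larger value does not show a stronger loss. Another Tet1 probe had a mean of -0.22 over both tissues, and the remaining one, not well above background in WT, had 0.21. The labels do not say which part of the gene was removed, and a probe outside it checks nothing about the genotype. Tet2 gave 0.12 ± 0.06 in cortex and 0.07 ± 0.06 in hippocampus (adjusted p = 0.335 and 0.544). The brightest Tet3 probe, which was not well above background in WT, was at least 1.08-fold higher in KO cortex and at least 1.04-fold higher in KO hippocampus, without passing (adjusted p = 0.234 and 0.436), and lay 0.57 below the median of all genes in cortex under median centring. Further Tet3 probes, also well above background in only 2 of the 4 groups, disagreed. A_51_P199339 had -0.34 in cortex and -0.30 in hippocampus, and A_52_P491273 had 0.23 and 0.34, so the direction of Tet3 is not settled. The list of TET, DNMT and demethylation enzymes did not pass in any comparison, with 16 of 32 members above 0 and 16 below 0 in cortex.

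In cortex, 2 genes were higher and 8 lower in KO. Sv2c, a synaptic vesicle glycoprotein (chromosome 13, 96729454 to 96729513), rose at least 4.45-fold from a WT signal not well above background, with a fitted ratio of 2.17 ± 0.11 and adjusted p = 0.0384. Mtap1b (now Map1b), a microtubule-associated protein of axons and dendrites (chromosome 13, 100192506 to 100192565), rose by 1.98 ± 0.09 (adjusted p = 0.0337). The largest fall was in Zfp874a, a zinc finger protein gene (chromosome 13, 67541780 to 67541839), at least 7.99-fold lower in KO, where it was not well above background (fitted ratio -3.26 ± 0.11, adjusted p = 0.0258). Trfr2 (now Tfr2), a transferrin receptor, fell by 1.65 ± 0.07. Pam, which amidates neuropeptides, fell by 1.51 ± 0.08, the zinc finger gene Zfp429 fell by 1.40 ± 0.08, Pgam2, the muscle form of phosphoglycerate mutase, fell by 1.18 ± 0.07, and the mitochondrial protein gene Fastkd3 fell by 1.12 ± 0.07 (adjusted p 0.0337 to 0.0474 for these 5). By the rule that chose them, both cortex arrays have the direction of these 8 genes. A further Mtap1b probe, well above background in all groups, did not bear out its rise (mean of 0.02 over both tissues), and no further Sv2c probe was well above background in more than 2 of the 4 groups.

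The next genes by p in cortex did not pass (adjusted p = 0.0536). Gdpd3 was at least 3.22-fold, Rfesd at least 1.61-fold, Dmrt2 at least 1.59-fold and Mtrr, methionine synthase reductase, at least 1.56-fold higher in KO over a WT signal not well above background. Zbtb17 and Akd1 were also not well above background in WT, and their bounds gave no fold. The protease inhibitor Serpina3n had a ratio of -2.38 ± 0.17 and the immediate-early gene Btg2 one of -1.03 ± 0.07.

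Of 40 immediate-early and activity-regulated genes, which neurons transcribe within minutes to hours of firing, 28 lay below 0 in KO cortex (median -0.17, camera adjusted p = 0.00292, adjusted p = 0.975 with an estimated correlation). None of them passed over all genes tested in limma, where 13 had an unadjusted p under 0.05, while 1 higher and 4 lower passed adjusted over the list alone. Npas4, an activity-dependent transcription factor, had -1.54 ± 0.16 (adjusted p = 0.0779) and the growth arrest gene Gadd45g had -0.67 ± 0.07. The study chose 6 of these genes on these samples, which is not independent evidence of their direction. All 6 lay below 0 (median -0.55, camera adjusted p = 0.00231, adjusted p = 0.975 with an estimated correlation), 1 of them lower adjusted over the list alone. After Npas4 came Fos with -0.75 ± 0.23, Arc with -0.67 ± 0.23, Egr2 with -0.43 ± 0.27, Egr4 with -0.36 ± 0.17 and Nr4a2 with -0.10 ± 0.09. Nr4a2 lay 0.11 above the median of all genes under median centring. The first cortex array did not show the list's shift: without cortex replicate 2 the 40 genes had a median of 0.07 (adjusted p = 0.894), the 6 had -0.14 (adjusted p = 0.101), and Egr2 and Nr4a2 had 0.07 and 0.04.

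Microglia markers were lower in KO cortex as a list, with 15 of 18 members below 0 (median -0.16, camera adjusted p = 0.000721, adjusted p = 0.975 with an estimated correlation) and 1 higher and 3 lower adjusted over the list alone. The complement genes C1qa and C1qb had -0.58 ± 0.08 and -0.55 ± 0.08. Trem2 had -0.54 ± 0.07, and Fcrls had 0.74 ± 0.06. All 15 striatal markers lay below 0 (median -0.28, camera adjusted p = 0.000450, adjusted p = 0.975 with an estimated correlation), 1 of them lower adjusted over the list alone. The dopamine receptor gene Drd1a (now Drd1) had -0.65 ± 0.14. Most of the striatal shift came from the first cortex array, with a list median of -0.45 against -0.10 on the second, and the call ended without the first. As given below, these markers were also higher in the cortex than in the hippocampus samples. The amount of striatum in each cortex sample was not tested. Choroid plexus markers, from the tissue that secretes cerebrospinal fluid, moved the other way, with 17 of 17 above 0 (median 1.28, camera adjusted p = 0.0224, adjusted p = 0.975 with an estimated correlation). Their call ended without cortex replicate 2 (median 0.55, adjusted p = 0.388), with a strict filter on dim probes (0.134) and without the array as a block (0.167), and no member passed adjusted over the list alone. Tmem72 was at least 1.41-fold higher in KO, and the transthyretin gene Ttr had 2.85 ± 1.39, the water channel gene Aqp1 1.52 ± 0.79 and Kl 1.37 ± 0.69. Under median centring camera called none of these 5 cortex lists (adjusted p = 0.138 to 0.990).

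The 10 calls in cortex rest on the whole set of arrays. Leaving out any 1 of the 4 arrays, giving the prior variance an intensity trend together with robust estimation, or keeping outlying local backgrounds left 0 genes in limma, with 1333 to 4049, 3270 and 1659 genes at an unadjusted p under 0.05 against 3473 in the fit reported, while Feature Extraction's processed signals gave 131 genes and the single-channel fit 669.

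**Figure D1:**
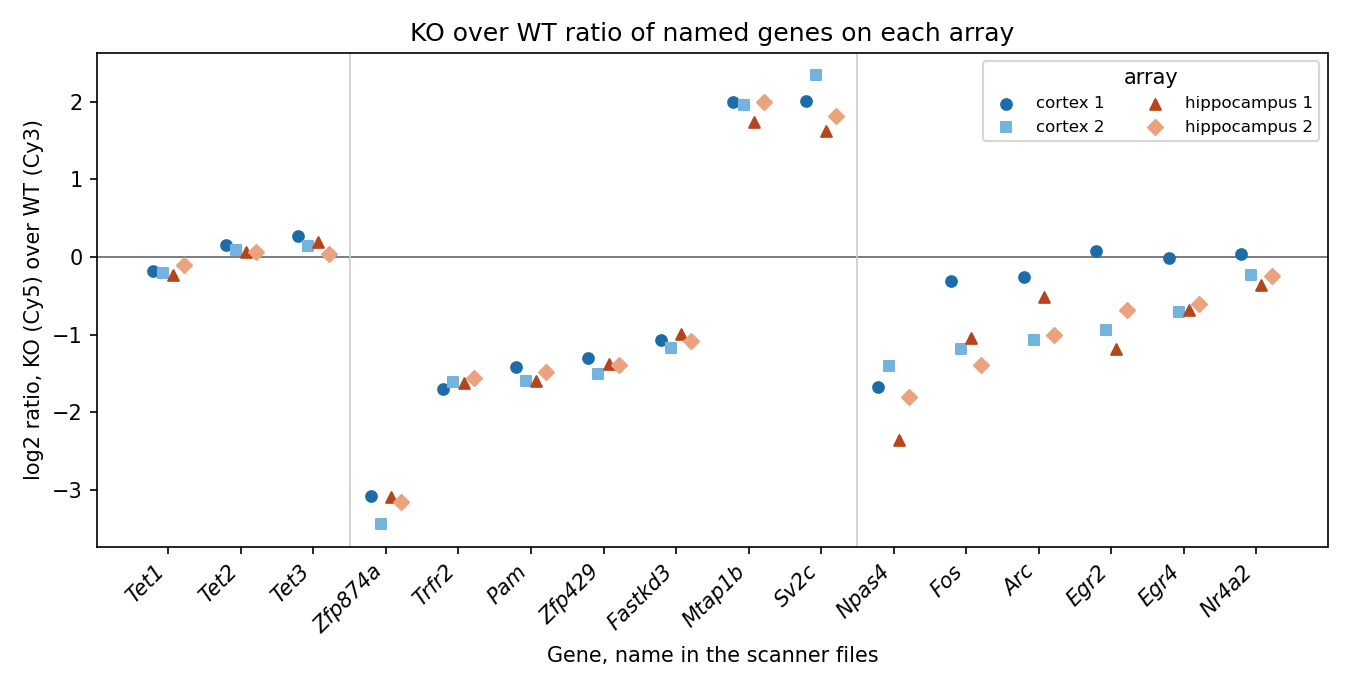
Log2 ratio of KO over WT of single genes on each of the 4 arrays (y axis) for the TET genes, some of the genes called in cortex or hippocampus (without Pgam2) and the 6 genes the study followed up (x axis), with vertical lines between these sets, one point per array and n = 2 arrays per tissue. Zfp874a lies between -3.44 and -3.08 on the 4 arrays, Mtap1b between 1.74 and 1.996 and Npas4 between -2.36 and -1.40, while Tet1 stays between -0.23 and -0.10.

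In hippocampus, 1 gene was higher and 2 were lower in KO. Mtap1b rose by 1.87 ± 0.09 (adjusted p = 0.0434), with the same disagreement between its probes as in cortex. Zfp874a was at least 8.56-fold lower in KO, where it was not well above background (fitted ratio -3.12 ± 0.11, adjusted p = 0.0316), and Trfr2 fell by 1.59 ± 0.07 (adjusted p = 0.0412). The genes next in order did not pass: Pam had -1.54 ± 0.08 (adjusted p = 0.0506), Zfp429 -1.38 ± 0.08, Fastkd3 -1.04 ± 0.07, the GABA transporter gene Slc6a13 -1.71 ± 0.10, the gap junction gene Gjb2 -1.49 ± 0.09 and the smooth muscle myosin gene Myh11 -0.90 ± 0.07. Gin1 had 1.02 ± 0.07, and Gdpd3 was at least 3.73-fold, Sv2c at least 2.59-fold and Rfesd at least 1.72-fold higher over a WT signal not well above background. Akd1, Zbtb17 and Wbscr25 were likewise not well above background in WT, and their bounds gave no fold.

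Immediate-early and activity-regulated genes were lower as a list in KO hippocampus too, with 29 of 40 below 0 (median -0.27, camera adjusted p = 0.000855, adjusted p = 0.961 with an estimated correlation). The median of these 40 genes was -0.14 on the first hippocampus array and -0.37 on the second. None passed over all genes in limma, and 1 higher and 6 lower passed adjusted over the list alone. Npas4 had -2.08 ± 0.16 (adjusted p = 0.0595), Btg2 -0.77 ± 0.07, Gadd45g -0.53 ± 0.07 and the kinase gene Plk2 0.38 ± 0.06. Of the 6 genes the study followed up, which is not independent evidence, all lay below 0 and all 6 were lower adjusted over the list alone (median -0.85, camera adjusted p = 0.000306, adjusted p = 0.961 with an estimated correlation). Fos had -1.22 ± 0.23, Egr2 -0.93 ± 0.27, Arc -0.77 ± 0.23, Egr4 -0.64 ± 0.17 and Nr4a2 -0.30 ± 0.09.

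Choroid plexus, thalamic, oligodendrocyte and endothelial markers had lower ratios as lists by camera in KO hippocampus, with no member called over all genes in limma. All 17 choroid plexus markers lay below 0 (median -1.45, camera adjusted p = 0.000683, adjusted p = 0.961 with an estimated correlation), among them Kcnj13 with -2.91 ± 1.08, Kl with -1.61 ± 0.69 and Igfbp2 with -1.02 ± 0.36. This came from 1 array: without hippocampus replicate 2 the median was 0.11 (adjusted p = 0.973). All 12 thalamic markers lay below 0 (median -0.48, camera adjusted p = 0.000449, adjusted p = 0.961 with an estimated correlation), with 2 lower adjusted over the list alone, Zic1 at -2.12 ± 0.35 and Tcf7l2 at -0.41 ± 0.06. Most of this came from the same array, since their median was -0.11 without hippocampus replicate 2 (adjusted p = 0.0368) and -1.02 without replicate 1. Oligodendrocyte markers had 16 of 17 members below 0 (median -0.23, camera adjusted p = 0.0172, adjusted p = 0.961 with an estimated correlation), with Enpp2 at -1.53 ± 0.67, Mag at -0.47 ± 0.19 and the myelin gene Mbp at 0.46 ± 0.16. Without hippocampus replicate 2 their median was 0.06 (adjusted p = 0.752). Endothelial and pericyte markers had 12 of 16 below 0 (median -0.24, camera adjusted p = 0.00455, adjusted p = 0.961 with an estimated correlation) and 4 lower adjusted over the list alone, including Cldn5 at -0.68 ± 0.10 and Vtn at -0.68 ± 0.11. This call ended without hippocampus replicate 2 (adjusted p = 0.0929), and both it and the oligodendrocyte call ended under median centring (adjusted p = 0.786 and 0.678).

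Interferon-response genes had 18 of 24 members below 0 in KO hippocampus (median -0.14, camera adjusted p = 0.00803, adjusted p = 0.961 with an estimated correlation), with 1 higher and 5 lower adjusted over the list alone. The immunoproteasome genes Psmb8 and Psmb9 had -0.43 ± 0.08 and -0.38 ± 0.07. Irf7 and Trim30a were not well above background in WT and their bounds gave no fold. Neuropeptides and growth factors were the 1 list called higher, with 21 of 28 above 0 (median 0.18, camera adjusted p = 0.0284, adjusted p = 0.961 with an estimated correlation) and 1 higher adjusted over the list alone. Cort, a somatostatin-like peptide gene, had 0.63 ± 0.09 and the galanin gene Gal had -0.57 ± 0.11. The call ended without hippocampus replicate 2 (median 0.04, adjusted p = 0.752), from Feature Extraction's processed signals (0.174), under median centring (0.160), with the mean of probes (0.0741) and without the array as a block (0.0543). Of the 3 genes called in hippocampus, 0 or 1 remained when any array was left out and 0 with an intensity trend and robust estimation together (3759 genes at an unadjusted p under 0.05 in limma, against 3892 in the fit reported), while 7 were called with outlying local backgrounds kept, 366 from Feature Extraction's processed signals and 984 in the single-channel fit.

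**Figure D2:**
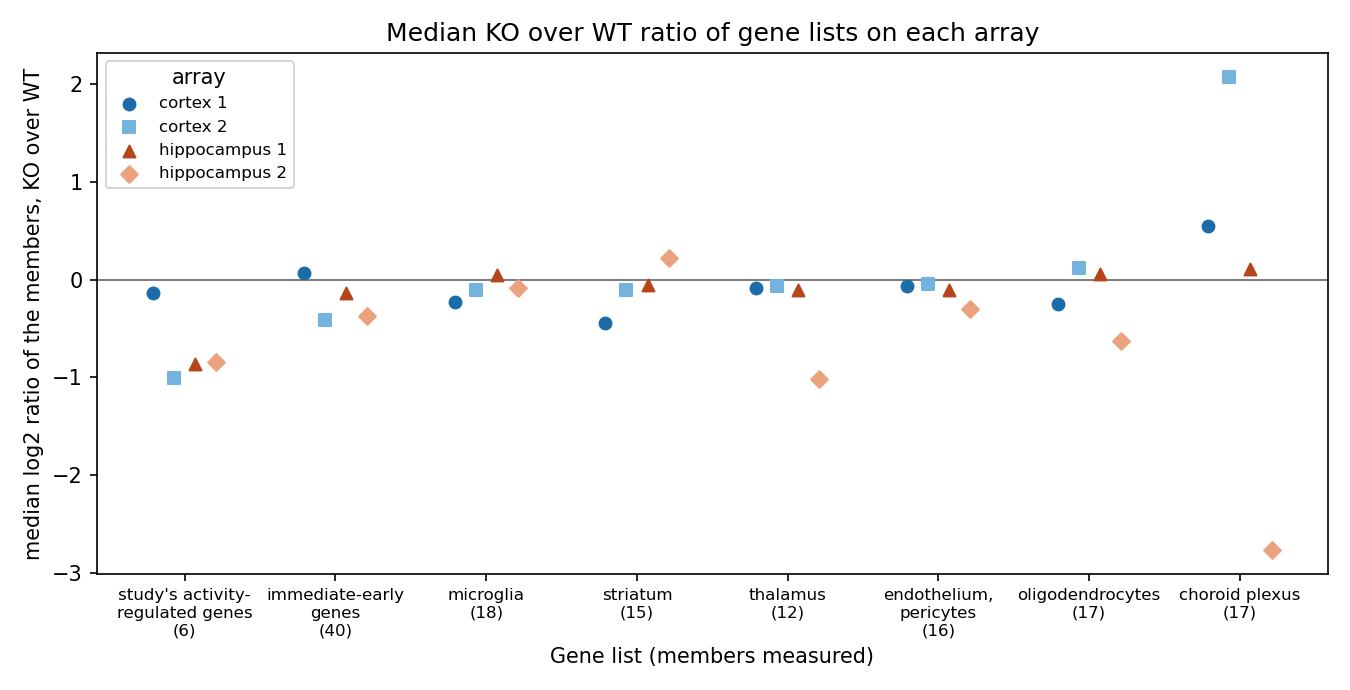
Median log2 ratio of KO over WT (y axis) of gene lists (x axis) on each of the 4 arrays (colours and markers), one point per array and n = 2 arrays per tissue. Choroid plexus markers run from -2.77 on the second hippocampus array to 2.07 on the second cortex array, whereas the 6 genes the study followed up lie between -1.01 and -0.14 on all 4 arrays.

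Taking the mean of both tissues, which uses all 4 arrays, 1169 genes were higher and 626 lower in KO. The excess of rises (65.1% of the called genes) depended on the filter on dim probes. With a strict filter 546 were higher and 453 lower (54.7%), and without a filter 1707 and 1533 (52.7%). Feature Extraction's processed signals went the other way, with 73.1% higher. The largest falls were in Zfp874a (-3.19 ± 0.07, adjusted p = 0.00578), in the protease inhibitor genes Serpina3n (-2.19 ± 0.12), Serpina3i (-1.84 ± 0.21) and Serpina1a (-1.58 ± 0.23), in the envoplakin gene Evpl (-2.07 ± 0.12), in Npas4 (-1.81 ± 0.11, adjusted p = 0.0146), in Prune2 (-1.79 ± 0.17) and in Trfr2 (-1.62 ± 0.05). The largest rises were in Gdpd3 (1.96 ± 0.09), Sv2c (1.94 ± 0.08), Mtap1b (1.92 ± 0.06, adjusted p = 0.00777), Spry2, an inhibitor of receptor tyrosine kinase signalling (1.46 ± 0.12), Arsk (1.44 ± 0.18), Mtrr (1.07 ± 0.06), Rnase4 (1.07 ± 0.07) and Rfesd (1.03 ± 0.05). By the rule that chose them, all 4 arrays have the direction of these 16 genes. Gdpd3, Sv2c, Spry2, Arsk, Mtrr and Rfesd were not well above background in WT, nor Zfp874a in KO, nor Serpina3i in KO cortex, and Serpina1a was so on 1 of the 2 WT cortex arrays. Their ratios are fitted values, and bounds exist only where given per tissue. Further probes for Arsk and Prune2 were well above background in at most 2 of the 4 groups. The Arsk probe reported has a like limit, as it was not well above background in WT, so probes do not settle the change of Arsk. Over the alternatives, median centring included, Arsk ran from 0.45 to 2.78 and Prune2 from -2.21 to -0.56.

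Over both tissues, 29 of the 40 immediate-early and activity-regulated genes lay below 0 (median -0.21, camera adjusted p = 0.00129, adjusted p = 0.946 with an estimated correlation). In limma 2 were higher and 6 lower over all genes, and 6 higher and 12 lower adjusted over the list alone. Npas4, Fos (-0.99 ± 0.16, adjusted p = 0.0387), Btg2 (-0.90 ± 0.05, adjusted p = 0.0137) and Gadd45g (-0.60 ± 0.05, adjusted p = 0.0224) fell, and Plk2 rose by 0.29 ± 0.05 (adjusted p = 0.0370). All 6 genes the study followed up lay below 0 (median -0.70, camera adjusted p = 0.000870, adjusted p = 0.946 with an estimated correlation). All 6 were lower adjusted over the list alone, which is not independent evidence, and Npas4 and Fos over all genes. Arc had -0.72 ± 0.16 (adjusted p = 0.0596), Egr4 -0.50 ± 0.12 (adjusted p = 0.0693), Egr2 -0.68 ± 0.19 (adjusted p = 0.0852) and Nr4a2 -0.20 ± 0.06 (adjusted p = 0.109), the last lying 0.02 above the median of all genes under median centring. Of 5 immediate-early and activity-regulated genes with a further probe well above background in all groups, 3 had a negative ratio on the brightest probe and a positive one on the further probe: Nr4a2 (0.17), Rgs2 (0.15) and Tiparp (0.41), named here after their values were seen.

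Among cell type markers, 14 of 18 microglia genes lay below 0 over both tissues (median -0.07, camera adjusted p = 0.0471, adjusted p = 0.946 with an estimated correlation). C1qa fell by 0.53 ± 0.05 and C1qb fell by 0.50 ± 0.05, while Fcrls rose by 0.76 ± 0.04, and under median centring the list's median was 0.04 above that of all genes. Endothelial and pericyte markers had 12 of 16 below 0 (median -0.15, camera adjusted p = 0.0343, adjusted p = 0.946 with an estimated correlation), and Cldn5, a tight junction gene of brain endothelium, fell by 0.59 ± 0.07 while Rgs5 had -0.33 ± 0.08 without passing. Both of these lists lost their call without cortex replicate 1 (adjusted p = 0.180 and 0.148) and without hippocampus replicate 2 (adjusted p = 0.196 and 0.0918). Thalamic markers had 10 of 12 below 0 (median -0.30, camera adjusted p = 0.00988, adjusted p = 0.946 with an estimated correlation), and Tcf7l2, not well above background in WT cortex, fell by a fitted 0.32 ± 0.05 while Zic1 had -1.03 ± 0.25 without passing. Their median was -0.082 without hippocampus replicate 2 (adjusted p = 0.0478), and their call ended with the mean of probes (adjusted p = 0.0568). Under median centring camera called none of the 5 lists of this comparison (adjusted p = 0.0760 to 0.646), and without a filter on dim probes it called neither microglia (0.188) nor endothelial (0.144) nor thalamic markers (0.0770). With outlying local backgrounds kept and without the array as a block, the microglia (0.0805 and 0.105) and endothelial calls (0.0591 and 0.0606) ended. The microglia call also ended from Feature Extraction's processed signals (0.0541) and with a strict filter (0.101). Among sex-linked markers, the Y-linked genes Ddx3y and Eif2s3y were well above background in all 8 samples, with ratios of -0.10 ± 0.08 and 0.16 ± 0.09 (adjusted p = 0.440 and 0.256). Uty was not well above background in WT (fitted ratio 0.07 ± 0.09), and its ratio lay 1.11 below the median of all genes under median centring. Xist and Kdm5d were not well above background in any group.

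The count over both tissues depended on the arrays and on the variance model. It was 0 or 1 with any array left out, 0 with an intensity trend in the prior variance and robust estimation together (5772 genes at an unadjusted p under 0.05 in limma, against 5552 in the fit reported), 3 with outlying local backgrounds kept, as in the version of the fit run first, 1162 from Feature Extraction's processed signals, 999 with probes measured on every array and 3314 in the single-channel fit.

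Whether KO acted differently in cortex and hippocampus was tested as the difference of their log ratios, in which a dye bias equal on all arrays cancels. Limma called 0 genes, with 740 at an unadjusted p under 0.05 against 818 expected by chance and a smallest adjusted p of 0.841, and median centring called 119. The smallest p-values belonged to genes with higher ratios in cortex: Slc6a13 (difference 1.80 ± 0.15), Gjb2 (1.44 ± 0.13), Krt79 (0.91 ± 0.10), the prostaglandin D synthase gene Ptgds (1.57 ± 0.17), Prdm12 (1.05 ± 0.12), Scin (0.78 ± 0.09), the lumican gene Lum (0.97 ± 0.11) and the sulfate transporter gene Slc13a4 (2.49 ± 0.31). In the other direction stood Abi3bp (-0.89 ± 0.09), Popdc3 (-0.88 ± 0.11), the fibrinogen gene Fgg (-0.80 ± 0.10), Agmat (-0.72 ± 0.09), Aldoart2 (-0.64 ± 0.09), the substance P precursor gene Tac1 (-0.77 ± 0.11), its receptor gene Tacr1 (-0.56 ± 0.09) and Fst (-0.53 ± 0.09). Of these, Prdm12, Scin, Fgg and Aldoart2 were not well above background in cortex WT and KO, and Abi3bp, Tacr1, Fgg and Aldoart2 were not in WT hippocampus. Their differences are fitted values that rest in part on background signal.

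As lists, 11 of the 30 tested differed between the tissues by camera and 0 with an estimated correlation or by fry. Choroid plexus markers differed most, with 17 of 17 members higher in cortex (median difference 2.49, camera adjusted p = 1.81e-11, adjusted p = 0.884 with an estimated correlation), among them Kcnj13 (4.22 ± 1.53), Kl (2.98 ± 0.97) and Tmem72 (a fitted 1.67 ± 0.38, as it was not well above background in WT cortex). The size of this difference hangs on single arrays, since the list's medians were 0.55 and 2.07 on the cortex arrays and 0.11 and -2.77 on the hippocampus arrays. Thalamic markers had 12 of 12 members above 0 (median 0.48, camera adjusted p = 0.000192, adjusted p = 0.884 with an estimated correlation), led by Zic1 (2.17 ± 0.50), and lost the call without hippocampus replicate 2 (median 0.08, adjusted p = 0.210). Cytosolic ribosomal proteins had 35 of 38 members below 0 by small amounts (median -0.13, camera adjusted p = 6.39e-07, adjusted p = 0.884 with an estimated correlation), with Rpl11 and Rpl3 at -0.23 ± 0.09 each. Their call ended without hippocampus replicate 1 (adjusted p = 0.223) and with outlying local backgrounds kept (median -0.036, above that of all genes, adjusted p = 0.593). Striatal markers had 12 of 15 below 0 (median -0.26, camera adjusted p = 7.44e-07, adjusted p = 0.884 with an estimated correlation), with Tac1 and Drd2 (a fitted -0.42 ± 0.09, as Drd2 was not well above background in WT hippocampus), although under median centring the list stood 0.0015 above the median of all genes (adjusted p = 0.799) and Drd2 stood 0.27 above it.

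Cortex and hippocampus differed strongly in WT, with 1202 genes higher in cortex and 1282 higher in hippocampus. All 15 striatal markers were higher in the cortex samples (median 2.60, camera adjusted p = 1.23e-20, adjusted p = 0.172 with an estimated correlation). The adenosine receptor gene Adora2a was at least 17.6-fold higher than in hippocampus, where it was not well above background. Rgs9 had a log2 ratio of cortex over hippocampus of 3.12 ± 0.17 and Tmem90a (now Syndig1l) one of 3.01 ± 0.14, and the dopamine receptor gene Drd2 was at least 2.27-fold higher. Other large rises were in Serpina9 (at least 15.6-fold), Dkkl1 (4.12 ± 0.20), Rasgef1c (3.68 ± 0.36), the sodium channel subunit gene Scn4b (3.27 ± 0.21) and Atp6ap1l (3.16 ± 0.27). Cortical layer markers had 19 members higher and 3 lower of 33 (median 0.91, camera adjusted p = 1.35e-08, adjusted p = 0.0670 with an estimated correlation), including Rspo1 (2.80 ± 0.10), 6330527O06Rik (now Lamp5, 2.11 ± 0.10) and Cplx3 (1.73 ± 0.10). Hippocampal field markers had 23 lower and 1 higher of 34 (median -1.16, camera adjusted p = 2.50e-17, adjusted p = 0.177 with an estimated correlation). Lct had -4.47 ± 0.17, Spink8 -4.09 ± 0.31, Shisa6 -3.39 ± 0.11 and the neuropeptide Y receptor gene Npy2r -2.82 ± 0.10. Dsp was at least 9.65-fold, Fibcd1 at least 9.19-fold, the LIM homeobox gene Lhx9 at least 8.55-fold and C1ql2 at least 8.19-fold lower in cortex, where they were not well above background.

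Neuronal activity and peptide genes also separated the WT tissues. Of the 40 immediate-early and activity-regulated genes, 14 were higher in cortex and 6 lower (median 0.22, camera adjusted p = 0.0112, adjusted p = 0.872 with an estimated correlation), with Npas4 at 1.36 ± 0.15, Nptx2 at 0.79 ± 0.07, Rgs2 at 0.75 ± 0.09 and Bdnf at -0.82 ± 0.12. The call ended without cortex replicate 2 (median 0.03, adjusted p = 0.424). Of the 6 genes the study followed up, 3 were higher in cortex over all genes and 5 adjusted over the list alone (median 0.88, camera adjusted p = 0.00928, adjusted p = 0.571 with an estimated correlation). Interneuron markers had 6 higher and 1 lower of 19 (median 0.23, camera adjusted p = 0.0112, adjusted p = 0.872 with an estimated correlation), with Tac1 at 2.62 ± 0.20, Crh at 1.88 ± 0.13, Vip at 1.17 ± 0.16 and Npy at 0.97 ± 0.13. Neuropeptides and growth factors had 11 higher and 6 lower of 28 (median 0.24, camera adjusted p = 0.0112, adjusted p = 0.872 with an estimated correlation), from the prodynorphin gene Pdyn at 1.43 ± 0.12 to the neurotrophin gene Ntf3 at -2.20 ± 0.08. Tac1 and Pdyn are also among the striatal markers, which were higher in the same cortex samples with a median of 2.60. Circadian clock genes had 3 higher of 21 (median 0.15, camera adjusted p = 0.00469, adjusted p = 0.255 with an estimated correlation), Rorb with 1.004 ± 0.08, Hlf with 0.47 ± 0.09 and Npas2 at least 1.28-fold higher. Npas2 lost its call in 6 alternatives and kept it in 9, and Hlf lost its call in 2 and kept it in 14. Cytosolic ribosomal proteins had 33 of 38 above 0 and none called by limma over all genes or adjusted over the list alone (median 0.09, camera adjusted p = 0.0173, adjusted p = 0.989 with an estimated correlation). Their call ended without cortex replicate 1, without hippocampus replicate 1 and with outlying local backgrounds kept (adjusted p = 0.0841, 0.257 and 0.592).

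The same tissues differed in KO by 1265 genes higher and 1202 lower in cortex. All 15 striatal markers were again higher (median 2.28, camera adjusted p = 1.33e-18, adjusted p = 0.174 with an estimated correlation), with Adora2a at 3.66 ± 0.21, Rgs9 at 2.93 ± 0.17 and Drd2 at 1.28 ± 0.07. Dkkl1 (3.79 ± 0.20), Serpina9 (3.39 ± 0.22), Scn4b (3.30 ± 0.21), Rasgef1c (3.06 ± 0.36) and Coch (2.68 ± 0.43) followed. Cortical layer markers had 19 higher and 4 lower of 33 (median 1.02, camera adjusted p = 7.46e-09, adjusted p = 0.0632 with an estimated correlation), with Rspo1 at 2.59 ± 0.10 and Stard8 at 1.33 ± 0.07. Hippocampal field markers had 23 lower and 2 higher of 34 (median -1.23, camera adjusted p = 1.57e-17, adjusted p = 0.174 with an estimated correlation). Lct had -4.37 ± 0.17, Spink8 -4.09 ± 0.31, Lhx9 -3.83 ± 0.08, Dsp -3.44 ± 0.22, Shisa6 -3.35 ± 0.11, Npy2r -3.29 ± 0.10 and the cytokine gene Il16 -3.11 ± 0.13. Neural progenitor and immature neuron markers had 4 lower and 2 higher of 21 (median -0.20, camera adjusted p = 0.0177, adjusted p = 0.218 with an estimated correlation). The dentate gyrus gene Prox1 had -1.82 ± 0.10, Hopx -1.17 ± 0.10, the cyclin gene Ccnd2 -0.71 ± 0.08 and the immature neuron gene Dcx 0.76 ± 0.10. The call ended with a strict filter on dim probes and with outlying local backgrounds kept (adjusted p = 0.136 and 0.141). In WT the list had 5 lower and 2 higher and did not pass (median -0.17, camera adjusted p = 0.0761).

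Immediate-early and activity-regulated genes in KO had 12 higher and 4 lower in cortex (median 0.37, camera adjusted p = 0.00188, adjusted p = 0.803 with an estimated correlation), with Npas4 at 1.90 ± 0.15, Egr1 at 1.22 ± 0.15 and Ptgs2 at -0.66 ± 0.09, and 4 of the 6 genes the study followed up were higher (median 1.18, camera adjusted p = 0.000400, adjusted p = 0.309 with an estimated correlation). Circadian clock genes had 6 higher of 21 (median 0.24, camera adjusted p = 0.000824, adjusted p = 0.185 with an estimated correlation), including Rorb at 1.13 ± 0.08 and Nr1d1 at 0.59 ± 0.07. Interneuron markers had 6 higher and 2 lower (median 0.22, camera adjusted p = 0.0189, adjusted p = 0.803 with an estimated correlation), with Crh at 1.49 ± 0.13 and Vip at 1.14 ± 0.16, and neuropeptides and growth factors had 10 higher and 5 lower (median 0.22, camera adjusted p = 0.0189, adjusted p = 0.803 with an estimated correlation). Both lists share members with the striatal markers, which had a median of 2.28 in the same samples. The interneuron call ended without hippocampus replicate 1 (adjusted p = 0.344), and that of neuropeptides without cortex replicate 1 or hippocampus replicate 1 (adjusted p = 0.0735 and 0.121). All 17 choroid plexus markers lay above 0 with none called by limma over all genes or adjusted over the list alone (median 2.04, camera adjusted p = 0.000824, adjusted p = 0.803 with an estimated correlation), and Kcnj13 had 4.005 ± 1.35 (adjusted p = 0.101). Endothelial and pericyte markers had 15 of 16 above 0 and none called by limma (median 0.18, camera adjusted p = 0.0203, adjusted p = 0.690 with an estimated correlation), a call that ended without cortex replicate 2 or hippocampus replicate 2 (adjusted p = 0.130 and 0.0581).

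Between the genotypes, 1860 genes were called in the same direction, 915 higher and 945 lower in cortex, and 2 in opposite directions. Independent lists of these sizes would share 93 and 94. The tissue ratios of WT and KO had r = 0.83 across genes, which are not independent replicates. WT and KO samples shared arrays, so part of the overlap may come from the arrays. Leaving out 1 array gave 713 to 1976 genes in WT and 628 to 1917 in KO, and fry called 5 and 7 lists where camera called 9 and 11.

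**Figure D3:**
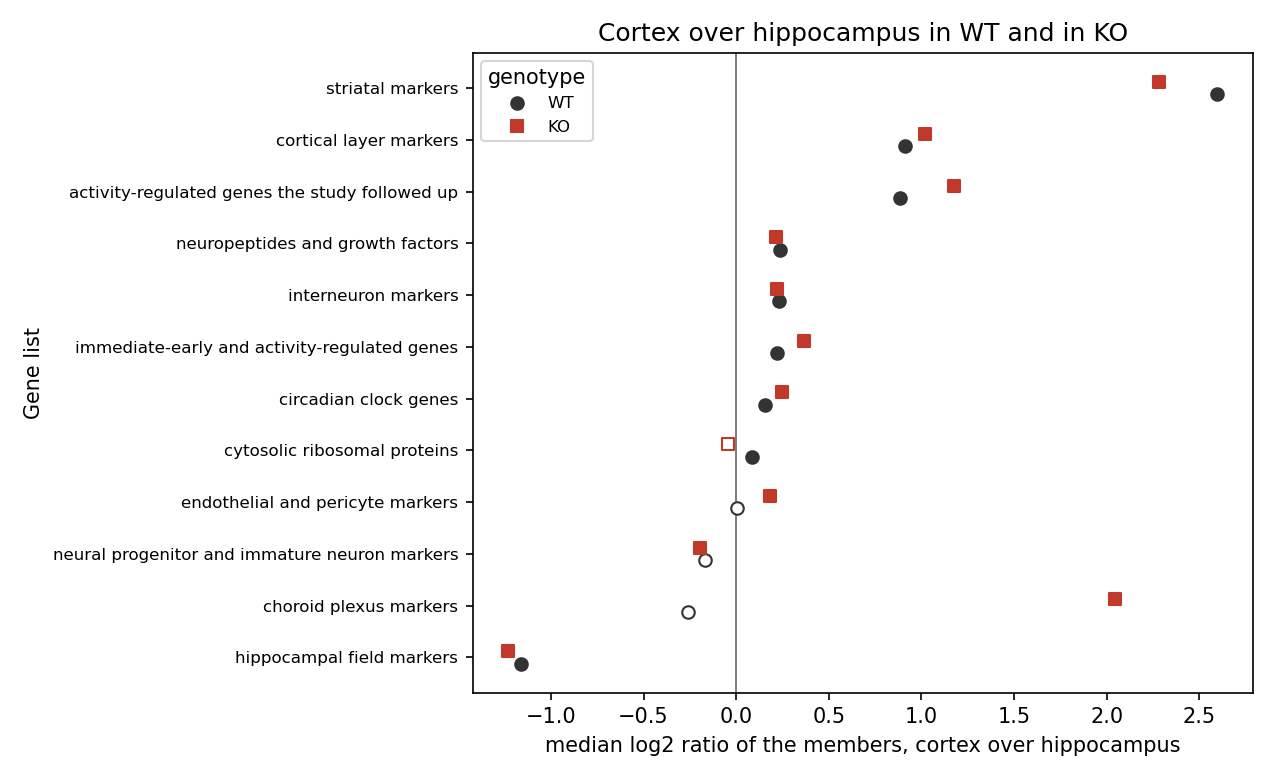
Median log2 ratio of cortex over hippocampus (x axis) of gene lists (rows) in WT and in KO (colours and markers), n = 2 samples per tissue and genotype. Filled markers passed camera's adjusted threshold and open markers did not. Striatal markers lie at 2.60 in WT and 2.28 in KO, and hippocampal field markers at -1.16 and -1.23.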

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

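The tests of dye bias, stress, choroid plexus and meninges were chosen only after the results were seen; the test of the spread between samples of one genotype was fixed before. For immediate-early genes the rules of the dye and stress tests were also rewritten after their first outcome, which had argued against both explanations. The first dye rule asked whether the list's array medians ranged more widely than in random lists, and they did (0.482 against a median of 0.0545, share 1e-04), but a bias equal on all arrays leaves room for further differences between arrays. The first stress rule took an adjusted p over 0.05 with few members called as evidence against, which a missed threshold is not.

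By camera, 11 lists differed in their KO to WT ratio between cortex and hippocampus, and none held with an estimated correlation (adjusted p = 0.884). Median differences, cortex minus hippocampus, were 2.49 for choroid plexus markers, 0.48 for thalamic markers, 0.37 for the 6 activity-regulated genes the study followed up, 0.31 for blood cell markers, 0.17 for endothelial and pericyte markers, 0.12 for interferon-response genes and 0.090 for heat shock genes. They were -0.26 for striatal markers, -0.16 for microglia markers, -0.13 for cytosolic ribosomal proteins and -0.075 for neuropeptides and growth factors. Camera's adjusted p was 0.00981 for blood cell and for endothelial markers, 0.000650 for interferon-response genes, 6.39e-05 for microglia markers, 0.0217 for the study's list, 0.0288 for neuropeptides and 0.0397 for heat shock genes. The blood cell and heat shock calls ended without cortex replicate 1 (adjusted p = 0.292 and 0.514) and without hippocampus replicate 2 (0.0634 and 0.403). The study's list lost its call without cortex replicate 1, hippocampus replicate 1 or hippocampus replicate 2 (adjusted p = 0.918, 0.180 and 0.0634), and neuropeptides without cortex replicate 2 or hippocampus replicate 2 (0.331 and 0.859). Endothelial markers lost it without the same 2 arrays (0.331 and 0.549), interferon-response genes without cortex replicate 2 (0.331), and microglia markers without hippocampus replicate 1 (0.0547). Under median centring striatal, heat shock and neuropeptide calls ended (0.799, 0.213 and 0.231). The blood cell and neuropeptide calls ended with outlying local backgrounds kept (0.118 and 0.0891), and that of the study's list with an intensity trend in the variance (0.107). The blood cell call also ended with a strict filter on dim probes (0.0676), the heat shock call with the mean of probes (0.0711), and the neuropeptide call with the mean of probes (0.0621) and from processed signals (0.145).

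Choroid plexus genes stood apart most. A dye bias equal on all arrays is argued against, since it cancels in the difference of 2.49 and would leave the arrays alike, whereas their medians ran from -2.77 to 2.07. Choroid plexus carried along in differing amounts is a candidate explanation: the list's median differed by 2.88 between the hippocampus arrays, more than between the tissues (2.64 as the difference of array means), and log2 Ttr levels ran from 11.98 to 16.2 in WT cortex and from 10.5 to 17.8 in WT hippocampus, with KO samples closer (16.6 and 17.3 in cortex, 11.3 and 13.8 in hippocampus). Meninges carried along is another, since 21 of 21 leptomeningeal markers, listed after the top genes had been seen and without Lum, had a positive difference (median 0.725, share of random lists 1e-04, the smallest that 10000 draws can give). The random lists were matched in brightness only. Leptomeningeal medians were 0.25 and 0.090 on the cortex arrays and -0.24 and -0.68 on the hippocampus arrays. Choroid plexus medians were 0.55, 2.07, 0.11 and -2.77 in the same order, so the lists did not move together within cortex or on hippocampus replicate 1. Meninges alone thus do not give the choroid plexus pattern. An effect of Tet1 on either tissue was not tested and stays open.

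Of 40 immediate-early and activity-regulated genes 29 lay below 0 over both tissues, 6 called lower and 2 higher (median -0.21, adjusted p = 0.946 with an estimated correlation), while on the first cortex array 26 lay above 0. The spread between samples of one genotype is a candidate explanation, as the list's median differed by 0.387 between the WT cortex samples, more than between genotypes over both tissues, and by 0.143 or less between replicates of the other groups. In hippocampus the replicates differed by 0.143 in WT and 0.047 in KO, less than the list's median change there. The comparison thus speaks for this candidate in cortex only. A dye bias equal on all arrays cannot be told apart from the change as a part of it, since the highest array median of 0.0707, on the first cortex array, lies above 0 by less than the SD of 0.145 over the others. Stress or handling was not decided under the rewritten rule, as glucocorticoid-response genes passed in neither direction (adjusted p = 0.909). An effect of Tet1 loss itself also remains open.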

How the results depend on the processing

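The single-channel fit of KO against WT and the version with outlying local backgrounds kept, which was run first, were tests chosen only after the results were seen. Where leaving out an array left a tissue with 1 array, that lone sample is assumed to vary like the other groups. Except where a reason is given, the cause was not tested.

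In limma the fit reported called 10 genes in cortex, 3 in hippocampus, 1795 in the mean of both tissues, 0 in their difference, 2484 between tissues in WT and 2467 in KO. Leaving out 1 array gave 0 to 0 in cortex, 0 to 1 in hippocampus, 0 to 1 in the mean, 0 to 0 in the difference, 713 to 1976 in WT and 628 to 1917 in KO, with fewer samples in each fit. A prior variance that follows intensity and robust estimation, changed together, gave 0 in cortex, hippocampus, mean and difference (3270, 3759, 5772 and 702 at an unadjusted p under 0.05) and 2560 and 2623 in the tissue comparisons. With outlying local backgrounds kept, the counts were 0, 7, 3, 0, 1796 and 1999. Without background correction they were 22, 16, 2284, 0, 2638 and 2839, and from the authors' values 22, 16, 2329, 0, 2644 and 2839. Feature Extraction's processed signals gave 131, 366, 1162, 0, 2417 and 2647. No filter on dim probes gave 27, 10, 3240, 0, 2069 and 2096, a strict filter 17, 14, 999, 0, 2072 and 2177 with fewer genes tested, and the mean of all probes 36, 2, 1749, 0, 2518 and 2394. Using only the arrays of the tissue or genotype concerned gave 0 in cortex (4049 at an unadjusted p under 0.05), 1 in hippocampus, 1468 in WT and 2626 in KO. The single-channel fit gave 669, 984 and 3314 for cortex, hippocampus and mean. With the replicate number as a block, the mean had 2316 genes, 1640 of them shared with the fit reported, the difference 0, and the tissue comparisons 2348 and 2383. The deviation of replicate 1 from replicate 2 had r = 0.16 between cortex and hippocampus over all genes, and the labels do not say that a number marks one animal. Dropping the array as a block gave 276, 430 and 2364.

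Centring each array on its median in place of loess called 13432, 13080, 14152 and 119 genes in the KO comparisons (1775 and 2862 between tissues), and put the median of all genes at 0.54 in cortex, 0.53 in hippocampus, 0.53 in the mean and -0.016 in the difference, where the fit reported had 0.035, 0.021, 0.026 and 0.0075. In the first 3 the median of all genes thus rose, but not every ratio did. In the mean Tet3 fell from 0.16 to -0.050 and Uty from 0.072 to -0.58, and genes called lower in cortex went from 8 to 2064. Subtracting 1 median per comparison therefore does not undo the change for each gene. Of the called genes 84.6%, 84.5%, 83.1% and 81.5% were higher in KO, against 20%, 33.3% and 65.1% in the first 3 comparisons of the fit reported. Of 40 reversals under this centring, 31 keep the reported sign relative to the medians of all genes. Before subtracting these medians, the values in cortex were Tet1 0.059, Tet3 -0.030, Arc 0.25, Egr2 0.19, Egr4 0.40, Nr4a2 0.65, Gadd45g 0.094, C1qa 0.12, C1qb 0.11, Trem2 0.15, Tac1 0.30, and medians of 0.46 for microglia and 0.45 for striatal markers. In hippocampus they were Tet1 0.094, Tet3 -0.069, Arc 0.13, Egr4 0.10, Nr4a2 0.46, Gadd45g 0.28, Cldn5 0.072, Vtn 0.097, Psmb8 0.0046, Mag 0.40, and 0.48 for oligodendrocyte markers. In the mean they were Tet1 0.077, Tet3 -0.050, Arc 0.19, Egr4 0.25, Nr4a2 0.55, Gadd45g 0.19, C1qa 0.17, C1qb 0.16, Cldn5 0.15, Rgs5 0.23, Ddx3y 0.53, Uty -0.58, and 0.57 for microglia and 0.46 for endothelial and pericyte markers. In the difference Drd2 had 0.25 and striatal markers -0.014, a direction that turned only relative to all genes.

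Other settings reversed few results. The mean of all probes gave 0.058 for Nr4a2 in cortex. Outlying local backgrounds kept gave -0.0014 for Tet2 in cortex, -0.018 for Uty in the mean and a median of -0.036 for ribosomal proteins in the difference. It put the medians of all genes there at -0.036, -0.022 and -0.078, so that Tet2 and Uty keep their sign relative to them (0.035 and 0.0039) and ribosomal proteins turned only relative to them (0.042). With 1 array left out, Egr2 in cortex ran from -0.94 to 0.071 and Nr4a2 from -0.23 to 0.036 (the highest without cortex replicate 2, where Uty had -0.042 in the mean), and oligodendrocyte markers in hippocampus from -0.63 to 0.060, the highest without hippocampus replicate 2. Over all alternatives, values of named genes kept direction and side of the threshold in 425 of 565 cases in cortex, 545 of 692 in hippocampus, 401 of 580 in the mean, 303 of 314 in the difference, 508 of 520 in WT and 447 of 457 in KO. In the mean 148 lost their call.

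Camera called 5, 8, 5, 11, 9 and 11 lists in the 6 comparisons, and 4 to 6, 7 to 11, 3 to 9, 8 to 12, 8 to 13 and 10 to 11 with 1 array left out. An estimated correlation left 0 lists in all 6, though it also missed a simulated shift of 40 genes. Fry gave 0, 0, 0, 0, 5 and 7. With outlying local backgrounds kept camera called 9 in cortex, without a filter on dim probes 2 in the mean, and without the array as a block 3 in the mean. The replicate block kept the 36 calls it could be tried on and gave 6 in the mean, 1 of them higher, 11 in the difference, 10 in WT and 12 in KO. Lists reported as called kept call and direction in 64 of 85 cases in cortex, 110 of 136 in hippocampus, 56 of 85 in the mean, 128 of 176 in the difference, 144 of 162 in WT and 175 of 198 in KO.

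Signal over background limits weakly expressed genes most, in WT above all, as the median Cy3 signal was only 1.35 to 1.43 times that of the negative controls.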

Other observations

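The tests of chromosome 13 and the list of major histocompatibility complex (MHC) class I genes were chosen only after the results were seen; the tests on splits of the arrays and on further probes were fixed before.

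Of 19 MHC class I genes, whose products present peptides at the cell surface, 18 lay below 0 in the mean of both tissues (median -0.34, camera p = 7.17e-10, p = 0.181 with an estimated correlation of 0.556), a list chosen from these data. In limma 12 were called lower and 0 higher, against 626 lower of all 16365 genes, and the list's median was -0.31 and -0.25 on the cortex arrays and -0.38 and -0.63 on the hippocampus arrays. Under median centring the list's median was 0.094, with 7 of 19 below 0, 6 called lower and 5 higher, or -0.44 relative to the median of all genes, and with outlying local backgrounds kept it was -0.30, with 0 called.

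Strongly changed genes, called in the mean of both tissues with a log2 ratio beyond 0.5 in size, gathered on part of chromosome 13 (60000001 to 70000000), where they made up 13 of 71 genes, 10 lower and 3 higher in KO, against 428 of 16311 on all chromosomes. Chance placement is argued against, since 41 of 1000 shuffles of gene positions had a window as full, although the fullest held 17. A strain segment carried along with the knockout may be a cause, as a hypothesis. It was tested only around Tet1, where on chromosome 10 the share of strongly changed genes was 3.64% (4 of 110 genes within 10 Mb) against 2.62% elsewhere (Fisher's exact p = 0.539), which decides nothing. Probes meeting a sequence difference between strains stay open too, as 1 strongly changed gene there has a further probe, and it had the same sign (1 of 1, Fastkd3 -0.77).

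The window on chromosome 13 was singled out after its genes had been seen. By number, windows on chromosomes 14 (50000001 to 60000000) and 17 (30000001 to 40000000) were fuller, with 14 of 131 and 14 of 193 genes and 17 of 1000 shuffles as full for each. The window on chromosome 17 holds 17 of the 19 MHC class I genes, which make up 5 of its 14 strongly changed genes. Strain segments and probes that meet a sequence difference between strains were not tested for these windows or for the MHC class I genes, and stay open there as on chromosome 13.

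The 4 array log ratios allow 8 splits by sign, too few for a share under 0.05. The real split, KO over WT on every array, gave 1795 genes in the mean of both tissues and the highest other split 0, so that 1 of 8 gave as many. Because KO was Cy5 on every array, this split cannot tell genotype from a dye bias equal on all arrays. For lists 7 of 8 gave as many as the 5 called, and the highest other gave 17, that of cortex replicate 1 and hippocampus replicate 2 against the remaining arrays. Of 199 called genes with a further probe well above background in all 4 groups, 66.8% had the same sign there, against 59.0% of all 2696 genes with one, and this leaves a dye bias or other error of single probes open. Among the 15 of these genes with a log2 ratio beyond 0.5 in size, 14 had the same sign (93.3%, r = 0.797), which goes against such an error for most of these 15 and says nothing of the others.

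Of the 30 lists tested, 12 passed in no comparison: by smallest adjusted p, astrocyte markers with 0.0760 (mean of both tissues, median -0.15, 15 genes), imprinted genes with 0.165 (46), germline genes with 0.263 (9), GABA signalling with 0.381 (21), calcium and cAMP signalling kinases with 0.448 (24), synaptic scaffolds with 0.514 (30), glucocorticoid-response genes with 0.593 (20), mitochondrial genes with 0.647 (33), TET, DNMT and demethylation enzymes with 0.655 (32), oligodendrocyte precursor markers with 0.692 (10), excitatory neuron markers with 0.720 (12) and glutamate receptors with 0.733 (25).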
